A study of Homo sapiens with 2 samples.

How the data were processed

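Gene expression was measured in 293T cells, an established human embryonic kidney cell line, on 2 dual-colour oligonucleotide microarrays. Per the labels' protocols, cells were treated with 10 µM Y27632, an inhibitor of the kinases ROCK1 and ROCK2, for 3 or 6 h. RNA was extracted with ISOGEN, amplified through an amino allyl procedure and coupled to cyanine dyes. On both arrays the untreated cells, given a time of 0 h, carried Cy5 and the treated cells carried Cy3. The titles of both arrays give the word control and a time, without the inhibitor, and the treatment was taken from the source name and the agent given for the Cy3 channel. There was no dye swap and 1 array per time, so no value has a replicate, no standard error between samples exists and no p-value is given. The labels do not say whether both arrays used the same preparation of control RNA.

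The deposited table held 1 log value, read here as a log2 ratio of the channels, for each probe and array, for 24267 probes. The values had 2 decimals and a median of 0 on each array as deposited. The background correction, the normalization within arrays, the spot filter, the log base and the numerator of the ratio are not given in the sources used here. A base of 10 would make 1 SD of all probes at 3 h a 2.39-fold difference, whereas base 2 makes it 1.30-fold. Base 2 was therefore assumed, and natural logarithms cannot be excluded from the values. Because the numerator is not known, signs below are those of the deposited values. A positive value means higher in treated cells if the ratio is treated over control, and lower in treated cells if it is control over treated. Turning the sign exchanges positive and negative throughout and leaves every size as it is. No spot intensities were used here, so the precision of single probes cannot be set by their brightness, and the number of arrays limits the precision of every value.

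Values were present for 20503 probes at 3 h and 20337 at 6 h, and 15.5% and 16.2% of probes had none. Both arrays gave a value for 19781 probes. The platform annotation used here, which dates from before many current symbols, gave 1 gene symbol for 13395 probes, several for 0 and none for 10872. Of the symbols, 10822 were current in the RefSeq gene table of assembly GRCh38.p14, 2446 were updated through a unique synonym, and 127 with an ambiguous synonym were kept as listed. A gene's value was the mean over its probes. This gave 10810 genes at 3 h, 10716 at 6 h and 10469 on both arrays. Probes of one gene differed with a within-gene SD of 0.31 at 3 h and 0.33 at 6 h, over 572 genes with 2 or more probes measured on both arrays. That SD is the only error available for a single gene's value. It covers probe differences and not the spread between cultures.

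The following choices were fixed before the values were seen. Genes were counted where the log ratio lay at least 1 unit from 0, a 2-fold difference in base 2, separately for each sign and for the difference of the 6 h and 3 h ratios. In that difference, a dye bias common to both arrays and a shared control cancel. A set of 49 gene lists was fixed, covering cytoskeleton and adhesion, transcriptional responses, cell cycle, stress, metabolism, RNA and protein handling, and markers of other cell types. The values of 1 list are not reported here. The median of each list was placed among the medians of 10000 random lists of the same size drawn from all measured genes. A list was said to stand apart below the 2.5th or above the 97.5th percentile, which chance gives for 2.45 of 49 lists of genes drawn at random. Members of a fixed list may vary together, which that number leaves out. Random lists were not matched on expression, since no spot intensities were used. These percentiles describe these arrays and are not tests across samples. Named genes were, among genes with a value on both arrays and leaving out placeholder symbols, the 10 highest and 10 lowest with one sign on both arrays, ranked by the smaller value. They further included the 6 highest and 6 lowest on each array, the 5 highest and 5 lowest differences, and 14 genes fixed by name. In each list that stood apart, the 4 members farthest out on the list's own side were also named. Members farther out on the other side were not picked by this rule. Genes named outside this rule are identified as chosen after their values were seen.

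The correlation of both arrays was computed across genes, which are not independent replicates. Lists apart at both times were compared with random lists that keep both values of each gene, a comparison added after the data were seen. Unchanged arrays that share 1 control were simulated 200 times from normal noise, whose ranks were then given the observed values of each array. Control and treated samples were given equal noise there, a choice that sets the simulated correlation. Covariances between different probes of a gene were bootstrapped over genes with 2000 resamples and are given with 95% intervals. The procedures were tested on simulated values for the 10469 genes. Of 200 genes changed by 1.5 units, 96% were recovered at 3 h and 95% at 6 h. Of the unchanged genes, 0.52% at 3 h and 0.44% at 6 h also passed the size. A list raised by 0.3 at 6 h lay above the 99.9th percentile. In 20 runs over a part of the lists, 5% of unchanged lists stood apart at 3 h. Simulated genes were independent with normal noise, so the shares of unchanged genes and lists follow from the settings. They check the code and do not cover lists whose members vary together. Alternatives covered the size threshold, the centring, the scale of each array, the probe rule, the unit counted, the gene filter and the background of the random lists. The log base, a count over genes with several probes and a background without olfactory receptor genes were added after the data were seen. A filter on dim spots was not run. Computations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.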

Results

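The series compared untreated 293T cells with 293T cells exposed to 10 µM Y27632 for 3 h or 6 h, on 1 dual-colour array per time. Y27632 blocks the kinases ROCK1 and ROCK2, which act on actomyosin contraction. The design asks which transcripts differ from control at each time, and hence also which ratios differ between the times. On both arrays the control cells were untreated and given a time of 0 h. The inhibitor therefore cannot be told apart from the time in culture, the handling or the vehicle. Log ratios were available for 10810 named genes at 3 h and 10716 at 6 h. Their SD across genes was 0.36 on each array, and the median gene lay at 0.02 on each. All signs are those of the deposited ratio, whose direction is not stated, so a positive or negative value is not called a rise or a fall. Sizes are in log2 units under the assumption of base 2.

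The named genes were ranked on both arrays by the smaller value. Farthest from 0 were the splicing kinases CLK1 and CLK3 on the positive side and the ribosomal protein gene RPS2 on the negative side. CLK1 (probe opHsV0400004943) had log ratios of 1.82 at 3 h and 1.77 at 6 h, which are 3.53-fold and 3.41-fold differences. CLK3 (probe H200005903) had 1.58 and 1.54. RPS2 (probe opHsV0400003898), a component of the small ribosomal subunit, had −1.33 and −1.46, and RPLP0, of the large-subunit stalk, had −1.09 and −1.10. Each of these genes had 1 probe, so the within-gene SD of 0.31 to 0.33 is the only estimate of its error. Over 572 genes with several probes, different probes of a gene correlated with r = 0.24 at 3 h and 0.18 at 6 h. Much of a value from 1 probe may therefore be particular to that probe.

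Other genes with positive values on both arrays included NUF2, a kinetochore component, at 1.12 and 1.33, and SMARCAD1, a chromatin remodeller, at 1.08 and 1.24. CCAR1, a regulator of apoptosis and the cell cycle, had 1.07 and 1.39. SHOC2, a scaffold of RAS to RAF signalling, had 1.07 and 1.08. SERAC1 had 1.92 and 1.23, and ITM2B had 1.05 and 1.04. The zinc finger genes ZNF708 and ZNF93 had 1.07 and 1.05 at 3 h and 1.17 and 1.40 at 6 h. On the negative side, CHST1, a carbohydrate sulfotransferase, had −1.32 and −1.25, and CELSR1, an atypical cadherin of planar cell polarity, had −1.27 and −1.20. DAGLA, which makes the endocannabinoid 2-arachidonoylglycerol, had −1.11 and −1.14. GJA5, a connexin, had −1.10 and −1.20, and the homeobox gene HOXC12 had −1.34 and −1.09. IL20, ZNF135 and PABPC5 completed the lowest genes, with 3 h values of −1.14, −1.41 and −1.44 and 6 h values of −1.33, −1.06 and −1.04. All genes named in this paragraph also had 1 probe each.

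In all, 16 genes lay at 1 or more on both arrays and 12 at −1 or less. Independent lists of the same lengths would share 0.31 and 0.59 genes. Simulated unchanged arrays sharing a control RNA shared 5.85 positive genes (95% range 2 to 11) and 8.63 negative genes (4.98 to 13). The positive count lay above that range and the negative count within it. Across 10469 genes the arrays correlated with Pearson's r = 0.65 and a Spearman coefficient of 0.68, and a shared control alone gave r = 0.49. The covariance was 0.0791, against 0.0602 simulated, a difference of 0.0189. All simulated values here assume equal noise in control and treated samples, and a noisier control would give a higher r. The noise was drawn from a normal distribution before the observed values were assigned by rank. A control with more extreme noise could give more shared genes, so the positive count does not argue against a shared control alone. Both arrays had the same dye orientation, and controls could not be split.

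**Figure D1:**
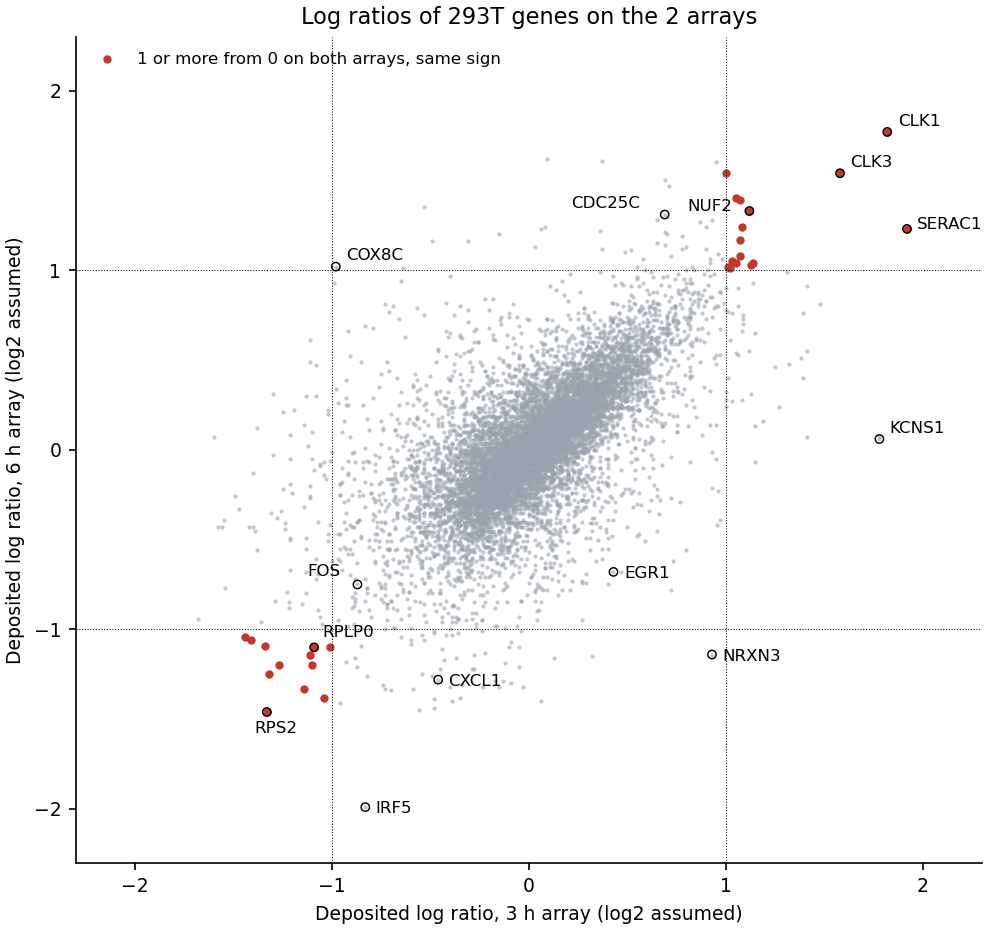
Deposited log ratio of each of 10469 genes on the 3 h array (x axis) and the 6 h array (y axis), in log2 units by assumption. Red points are the 16 and 12 genes at least 1 unit from 0 with the same sign on both arrays. Dotted lines mark 1 and −1, and labelled open circles are named genes. CLK1 and CLK3 are the highest of the named genes by the smaller of their values.

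The genes of the inhibited kinases lay within 1 unit of 0. ROCK1 had log ratios of 0.14 at 3 h and 0.41 at 6 h, and ROCK2 had 0.39 and 0.38. Targets of SRF and its actin-sensing cofactors MRTF had medians of −0.14 and −0.12, with 13 and 14 of 19 genes negative. These lay at the 3.94th and 6.77th percentiles and did not stand apart. TAGLN had −0.42 and −0.40, MYL9, a myosin light chain, had −0.16 and −0.63, and SRF itself had 0.12 and 0.15. Targets of the mechanosensitive coactivators YAP and TAZ had medians of −0.15 and −0.03 over 17 genes, at the 3.77th and 31.8th percentiles. Within them, CCN1 had 0.41 and 0.54 and CCN2 had 0.55 and 0.31, on the positive side, while AMOTL2 had −0.44 and −0.66. ANKRD1 had no value on either array, and ACTB and ACTG1 had no named probe in the annotation used here. TAGLN and AMOTL2 were chosen after their values were seen.

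At 3 h, 174 genes lay at least 1 unit from 0, of which 71 were positive and 103 negative. This balance depended on the threshold, with 527 positive and 485 negative genes at 1.5-fold. The rankings that follow are among genes with a value on both arrays and without placeholder symbols. The highest values were those of SERAC1 and CLK1, then KCNS1, a potassium channel subunit, and BTN3A1, a butyrophilin, both at 1.78. The pseudogene KLRA1P had 1.48. The lowest were FOXN4, a forkhead transcription factor, at −1.68, TMEM204 at −1.60, FOLR3 at −1.58, the TNF receptor gene TNFRSF1B at −1.56, the lipoxygenase gene ALOX12 at −1.55 and DSCR4 at −1.54. None of these lowest genes was past the size at 6 h: FOXN4 had −0.94, TMEM204 0.07, FOLR3 and TNFRSF1B −0.43, ALOX12 −0.39 and DSCR4 −0.77. Nor were KCNS1 at 0.06, BTN3A1 at 0.07 and KLRA1P at 0.81, whereas SERAC1 and CLK1 were. Of the 174 genes, 142 had a value on both arrays.

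Of the 49 gene lists, 13 stood apart at 3 h, against 2.45 by chance, 9 on the negative and 4 on the positive side. Immediate early genes, the transcription factors and regulators induced first by growth factors and stress, had a median of −0.24, outside the random range of −0.13 to 0.16. Of 28 measured members 24 were negative and none reached −1. JUN had −0.91, FOS −0.87, the stress factor ATF3 −0.75 and MYC −0.60, whereas EGR1 had 0.43. Feedback genes of MAPK signalling had a median of −0.29 with 14 of 15 negative, among them DUSP6, an ERK phosphatase, at −0.48, EPHA2 at −0.60, SPRY1 at −0.40 and IER3 at −0.39. This list shares 4 genes with the immediate early list, as do the targets of cAMP and CREB, whose median was −0.25 with 8 of 10 negative. The latter included PPARGC1A at −0.95, NR4A3 at −0.55 and NR4A1 at −0.25. TGF-beta targets had a median of −0.26 with 10 of 15 negative, among them BMP2 at −0.71, BMP4 at −0.40, the cell cycle inhibitor CDKN1A at −0.40 and CDKN2B at −0.39. NF-kB and inflammatory genes had a median of −0.19 with 13 of 17 negative, including LIF at −0.47 and CXCL1 at −0.46.

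A further 8 lists stood apart at 3 h. Focal adhesion and integrin genes had a median of −0.17 with 14 of 21 negative, among them ITGB3 at −0.53, ITGB5 at −0.43 and ITGA2 at −0.41. Axon guidance genes had a median of −0.20 with 17 of 23 negative, including SEMA3A at −0.88, UNC5B at −0.70 and EFNB1 at −0.53. Cytosolic ribosomal protein genes had a median of −0.20 with 11 of 15 negative, and RPS2 and RPLP0 were the 2 at or below −1, followed by RPL35 at −0.66 and RPLP1 at −0.54. In sets by symbol stem looked at after the data were seen, 28 RPL genes had medians of 0.00 at 3 h and −0.03 at 6 h. The 17 genes with the RPS stem had −0.12 and −0.09. The RPL stem leaves out RPLP0 and RPLP1, and the RPS stem would also take in RPS6K kinase genes. Kidney epithelial markers had a median of −0.30 with 9 of 11 negative, including LHX1 at −0.51, AQP1 at −0.50, CDH16 at −0.44 and PAX8 at −0.38. On the positive side, hypoxia genes had a median of 0.22 with 11 of 18 positive, led by the glucose transporter gene SLC2A3 at 0.87, ERO1A at 0.60, BNIP3 at 0.55 and P4HA1 at 0.47. Spliceosome and RNA-binding genes had 0.21 with 12 of 18 positive. CLK1 led them at 1.82, followed by SRSF5 at 0.82, CLK4 at 0.68 and SF3B1 at 0.64. The 10 genes with the SRSF stem, also looked at after the data were seen, had medians of 0.08 at 3 h and −0.0075 at 6 h. Proteasome genes had 0.21 with 11 of 16 positive, led by PSMA3 at 0.64. Genes of G2/M and mitosis had 0.19 with 22 of 29 positive, among them CDC25C, the phosphatase that activates CDK1, at 0.69, and HMMR and RACGAP1 at 0.61 and BUB1 at 0.52. With the mean in place of the median, the focal adhesion, hypoxia, proteasome, NF-kB and kidney lists no longer stood apart at 3 h, while oxidative phosphorylation and G1/S genes on the positive side and endothelial markers on the negative side newly did. Beside the negative lists, 123 olfactory receptor genes, a family looked at after the data were seen, had a median of −0.19. The remaining 36 lists had medians from −0.19 to 0.22.

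At 6 h, 153 genes lay at least 1 unit from 0, with 75 positive and 78 negative, and at 1.5-fold 603 were positive and 454 negative. The genes named here as highest and lowest are those with a value on both arrays, leaving out placeholder symbols. CLK1 and CLK3 were again among the highest, with KLHL32 at 1.61 and ZNF66 at 1.60. The endosome tethering gene EEA1 had 1.54 and the calcium-binding protein gene S100A3 had 1.5. The lowest were IRF5, an interferon regulatory factor, at −1.99, then RPS2, RNF17 at −1.45, the sperm tail gene ODF1 at −1.44, the phospholipase gene PLB1 at −1.41 and TSGA10IP at −1.40. At 3 h, EEA1 had 1, ZNF66 0.95 and PLB1 −0.96, while KLHL32 had 0.37, IRF5 −0.83, RNF17 −0.56, ODF1 −0.48 and TSGA10IP 0.06. Of the 153 genes, 130 had a value on both arrays.

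At 6 h, 8 lists stood apart, 5 on the negative and 3 on the positive side, again against 2.45 by chance. Immediate early genes had a median of −0.32 with 22 of 29 negative. FOS had −0.75, JUN −0.70, EGR1 −0.68 and JUND −0.64, MYC had −0.37 and JUNB −0.24. TGF-beta targets had a median of −0.26 with 12 of 16 negative, led by CDKN2B at −0.87, the inhibitor of differentiation ID1 at −0.56 and PMEPA1 at −0.54. NF-kB and inflammatory genes had a median of −0.21 with 9 of 15 negative, and the chemokine gene CXCL1 at −1.28 was the 1 member past the size. RELB had −0.45, and CXCL2 and CXCL3, closely related paralogs whose probes may not tell them apart, both had −0.42. All 15 feedback genes of MAPK signalling were negative, with a median of −0.19, including DUSP6 at −0.54, PHLDA1 at −0.38, and CCND1 and SPRY2 at −0.37. This list lay at the 2.62th percentile, and so did not stand apart, when each gene was given by its probe farthest from 0. All 8 endothelial markers were negative, with a median of −0.37, among them CDH5 at −0.55, PECAM1 at −0.54, KDR at −0.42 and ESAM at −0.38. The median of the 123 olfactory receptor genes was −0.22 at this time.

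On the positive side at 6 h, G2/M and mitosis genes had a median of 0.25 with 22 of 29 positive. CDC25C had 1.31, the spindle checkpoint kinase gene TTK 0.91, HMMR 0.79 and RACGAP1 0.77. Cholesterol synthesis genes had a median of 0.25 with 13 of 17 positive, including IDI1 at 0.53, SC5D at 0.52, HMGCS1 at 0.48 and CYP51A1 at 0.37. Genes of actin nucleation and branching had a median of 0.24 with 14 of 19 positive, led by CAPZB at 0.93, ARPC3, a subunit of the Arp2/3 complex, at 0.68, and the capping protein genes CAPZA1 and CAPZA2, both at 0.41, paralogs whose probes may not tell them apart either. The remaining 41 lists had medians from −0.19 to 0.21. In all, 5 lists, some of which share genes, stood apart on the same side at both times, against 0.49 (95% range 0 to 2) among random lists that keep both values of each gene together: immediate early genes, TGF-beta targets, NF-kB and inflammatory genes and MAPK feedback genes on the negative side, and G2/M and mitosis genes on the positive side. With means, the NF-kB list left this set, and ribosomal protein genes and endothelial markers joined it on the negative side. Blood cell markers with means and liver markers with the probe farthest from 0 newly stood apart on the negative side at 6 h.

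**Figure D2:**
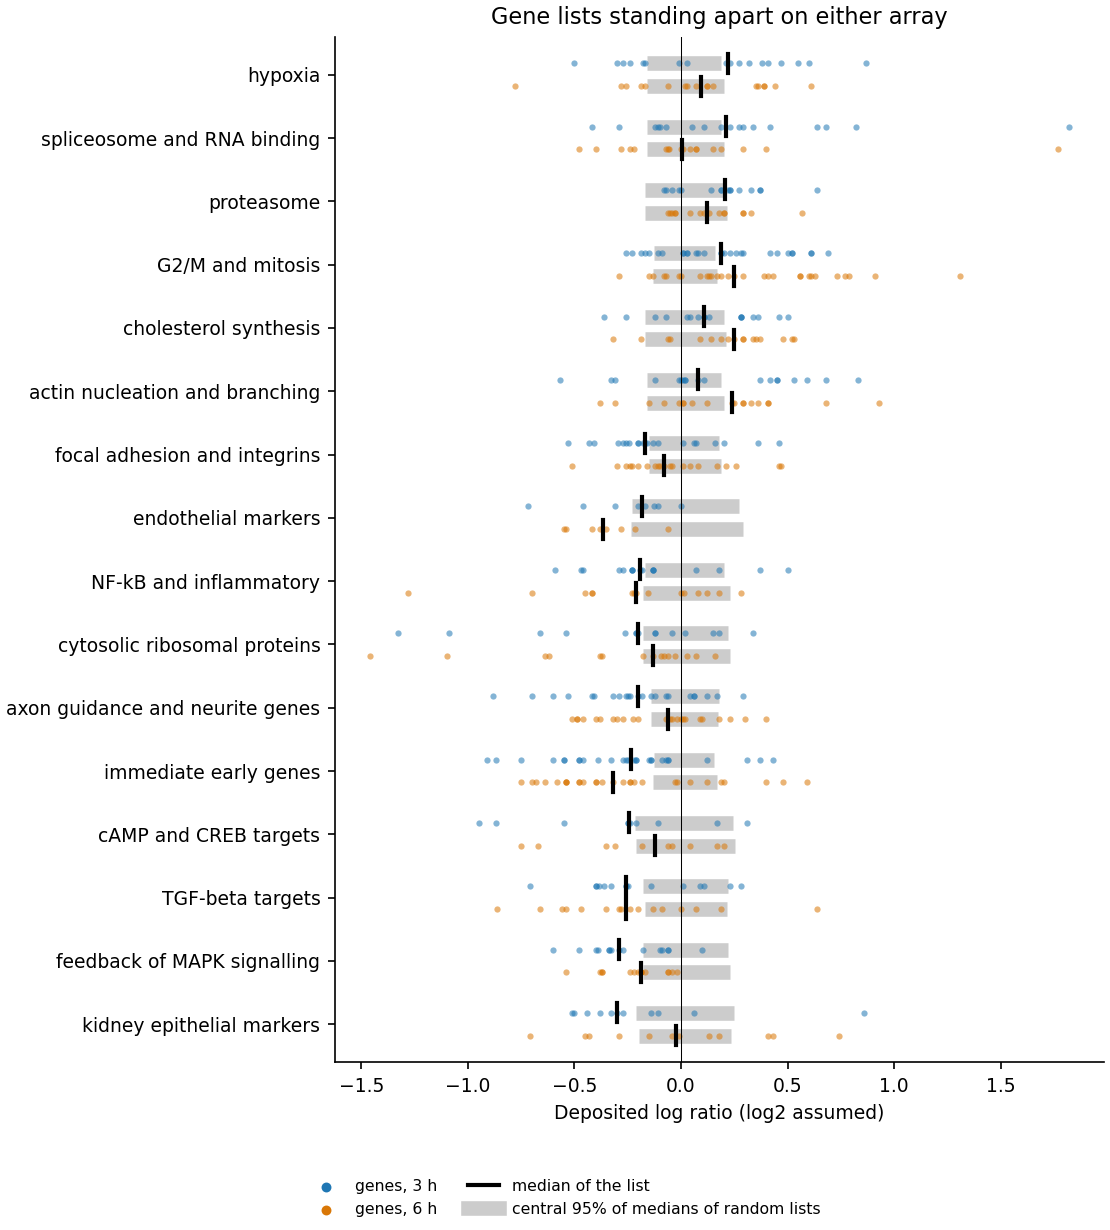
Log ratios (x axis, log2 units by assumption) of the genes in each list that stood apart at 3 h or 6 h. Points are genes at 3 h (blue) and 6 h (orange), black ticks are list medians, and grey bars span the central 95% of medians of 10000 random lists of the same size; the median of immediate early genes lies left of its bar at both times, at −0.24 and −0.32, and that of G2/M genes right of it, at 0.19 and 0.25.

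The difference of the ratios, 6 h minus 3 h, was at least 1 unit for 126 of 10469 genes, of which 81 were positive and 45 negative. At 1.5-fold, 319 were positive and 283 negative. The largest were NRXN3, a neurexin, at −2.07, and COX8C, a cytochrome oxidase subunit, at 2. KCNS1 and BTN3A1 had −1.72 and −1.71, the secreted WNT antagonist gene SFRP4 −1.5 and the uncoupling protein gene UCP1 −1.47. On the positive side, SPOCK3 had 1.92, FGD6 1.88, the channel gene BEST2 1.72 and TMEM204 1.67. EGR1 had 0.43 at 3 h and −0.68 at 6 h, a difference of −1.11. With 1 array per time, the time and the array cannot be told apart.

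Of the lists, 4 stood apart in this difference, against 2.45 by chance. G2/M and mitosis genes had a median difference of 0.15, outside the random range of −0.09 to 0.08, with 24 of 29 positive. CDC25C had 0.62, BUB1B 0.49, TTK 0.39 and KIF2C 0.32. Spliceosome and RNA-binding genes had a median of −0.20 with 16 of 18 negative, outside the range of −0.11 to 0.11. SRSF5, a splicing factor, had −0.89, CLK4 −0.39, SNRPA −0.25 and SF3B1 −0.24, while CLK1 had −0.05. NF-kB and inflammatory genes had a median of −0.14 with 9 of 14 negative, led by CXCL1 at −0.82 and NFKBIA at −0.22. Extracellular matrix genes had a median of 0.10 with 13 of 22 positive, led by POSTN at 0.77, COL6A2 at 0.63, LOXL2 at 0.40 and TNC at 0.35. The other 9 were negative, among them LOX at −0.58 and COL6A3 at −0.43, both chosen after their values were seen. With means in place of medians, the NF-kB and matrix lists did not stand apart, at the 13.3th and 87.7th percentiles, and kidney epithelial markers newly did, at the 98.6th. Immediate early genes had a median difference of 0.07 and did not stand apart. The remaining 45 lists had medians from −0.10 to 0.10.

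**Figure D3:**
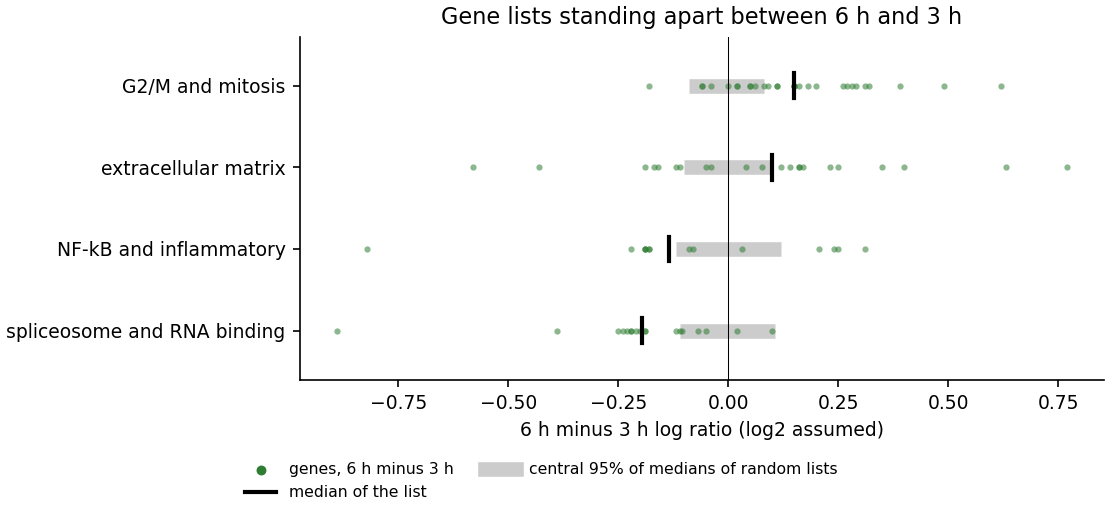
Difference of the 6 h and 3 h log ratios (x axis, log2 units by assumption) for the genes of the 4 lists that stood apart. Points are genes, black ticks are list medians and grey bars span the central 95% of medians of 10000 random lists of the same size; 24 of 29 G2/M genes lie right of 0 and 16 of 18 spliceosome genes left of it.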

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

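All tests in this part except the overlap of independent lists were chosen after the results were seen. Signs are those of the deposited ratio.

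Of the genes named by the rule, 10 had opposite signs at 3 h and 6 h and differed by at least 1 unit, and 91 of all genes did. Since the rule names the largest differences, the count of 10 follows largely from it. TMEM204 at 6 h (0.07) and TSGA10IP at 3 h (0.06) lay near 0. The differences were not tested, since each time has 1 array. They were 1.67 for TMEM204, −1.46 for TSGA10IP, −2.07 for NRXN3, −1.5 for SFRP4, −1.47 for UCP1, 2 for COX8C, 1.92 for SPOCK3, 1.88 for FGD6, 1.72 for BEST2 and −1.11 for EGR1. Probes with a value on a single array, which enter no count of genes past the size on both arrays, were past the size in 65 of 722 cases at 3 h (9%) and 56 of 556 at 6 h (10.1%), against 1.91% and 2% of probes with both values. Probes without a gene symbol were past the size in 246 of 8986 cases at 3 h (2.74%) and 277 of 8923 at 6 h (3.10%), against 1.70% and 1.52% of named probes.

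The arrays shared 16 positive and 12 negative genes past the size, at least 20.3 times the overlap of independent lists, which argues against chance overlap. A candidate explanation is a bias of single probes that both arrays share, since the dyes had the same orientation. Over 572 genes with several probes, the 3 h and 6 h values covaried between different probes of a gene only 0.307 times as much as for the same probe (95% interval 0.216 to 0.399), which leaves this bias as a part of the agreement, although probes for different transcripts of a gene would give the same. The covariance between different probes was 0.0249 (0.0171 to 0.0334), above 0, which argues against independent biases of single probes as the whole cause. A control RNA common to both arrays stays open too. Alone and with equal noise assumed it gave r = 0.494, below the observed 0.649, but a noisier control would give more. The parts cannot be told apart with 1 array per time. A treatment effect common to both times, or an effect of time or handling since the 0 h control, stays among the open explanations.

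Immediate early genes had negative medians on both arrays. A candidate explanation is that dim probes lean to the negative side. Olfactory receptor genes, which a kidney cell line is expected to express little, had medians of −0.19 and −0.22, below all 10000 random lists of their size on each array. Among random lists of these 123 genes, the immediate early median lay at the 20.9th percentile at 3 h and the 7.38th at 6 h. A lean of this kind would be large enough to give such medians if the immediate early genes were dim. Whether they were dim is not known without spot intensities, so the comparison cannot decide. The other negative lists that stood apart at both times also lay within that range, at the 22.6th and 32.9th percentiles for TGF-beta targets at 3 h and 6 h, the 13.3th and 58.1th for MAPK feedback genes and the 42.4th and 52.7th for NF-kB genes. An effect of Y27632 on these genes was not excluded, nor was one of time or handling since the 0 h control. The same lean would place lists of brighter genes on the positive side of random lists. With olfactory receptor genes left out of the random lists, the positive lists at 3 h and 6 h kept their calls, except the proteasome list at 3 h (97.4th percentile). Other dim genes stayed in that background, so the lean is open for the positive lists too.

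The CLK family was the highest of 525 families of at least 4 genes with a common symbol stem, with medians of 1.31 at 3 h and 1.30 at 6 h. In 1000 reshuffles of genes among families, which keep each probe's own bias, no family reached a smaller median above 0.80, which argues against chance and against independent probe biases. The next family, SMARCA, had 0.56. Probes of paralogs that bind one another's transcripts stay open, since no probe sequences were used: CLK4 had 0.29 at 6 h, 1.48 below CLK1. The hypothesis that Y27632 moves CLK transcripts as a group rests on 1 probe per gene. It cannot be told apart from an effect of time or handling since the 0 h control.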

How the results depend on the processing

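Counts of genes past the size depended on the threshold and on the log base, by construction. In the order 3 h, 6 h, both arrays and 6 h minus 3 h, the main counts were 174, 153, 28 and 126. A threshold of 1.5-fold gave 1012, 1057, 389 and 602, and 3-fold gave 8, 7, 1 and 13. The balance of signs depended on these choices and on the unit counted. At 3 h, 71 positive and 103 negative genes became 527 and 485 at 1.5-fold and 221 and 221 probes. On both arrays 16 and 12 became 264 and 125 at 1.5-fold and 104 and 36 probes. Read as natural logarithms, an alternative added after the data were seen, the 2-fold counts were 633, 640, 213 and 416, and in base 10, also added, 3577, 3744, 1971 and 1987. Counting probes, with or without a gene name, gave 442, 451, 140 and 283. Restricting to genes with 2 or more probes, also added, left 6, 6, 0 and 3 of 748, 747, 739 and 739 genes. All 28 genes past the size on both arrays therefore rest on 1 named probe each. Fewer genes and less varied means over probes would both lower these counts, by amounts that were not tested. Centring on the median of genes, equal spread of both arrays, the probe farthest from 0 and genes with a value on both arrays kept every count within 1.5 times. Subtracting each array's median over probes moves nothing, since it is 0. Counts of lists standing apart stayed within 1.5 times under all 6 alternatives, as did the correlation, between 0.65 and 0.68. Of the list medians under alternatives, 861 kept their call, 12 no longer stood apart and 9 newly did. The matrix list kept its call in 3 of 6 alternatives and the proteasome list in 3 of 6. The cause of these changes was not tested. No paired analysis was possible because each group has 1 array. A filter on dim spots was not run, so signal over background limits every value here to an unknown degree. Turning the sign exchanges 71 with 103, 75 with 78, 16 with 12 and 81 with 45.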

Other observations

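The following gene families, taken by symbol stem and not among the fixed lists, were chosen after their values were seen. The highest of 525 families reached up to 0.80 in 1000 reshuffles of genes, by the smaller of its medians. The 4 SMARCA genes lie within what chance gives the highest family. Medians of small families vary most, so this bound cannot judge larger families such as the 278 ZNF genes. No bound was set by family size, and the negative families were not tested. All 9 measured genes with the IFT stem, named for intraflagellar transport, which builds cilia, were positive on both arrays. Their medians were 0.42 at 3 h and 0.46 at 6 h, and IFT74 had 1.06 and 0.90, IFT88 0.70 and 0.75, and IFT81 0.65 and 0.81. The 4 SMARCA chromatin remodeller genes had medians of 0.56 and 0.61, led by SMARCA5 at 0.83 and 0.87. The 6 genes of the origin recognition complex had 0.37 and 0.43, 5 of them positive on both arrays, with ORC1 at 0.62 on both arrays. The 278 genes with the ZNF stem had 0.12 and 0.16, and 166 of them were positive and 58 negative on both arrays. On the negative side, the 4 LRFN synaptic adhesion genes had −0.42 and −0.36, and 5 genes with the CSF stem, 4 of them negative on both arrays, had −0.35 and −0.38, among them the growth factor receptor gene CSF1R at −0.77 and −0.47. Of 5 CEACAM adhesion genes with values on both arrays, 3 had a higher value at 6 h: CEACAM1, CEACAM3 and CEACAM4 had −0.59, −0.71 and −0.54 at 3 h and 0.00, 0.01 and 0.03 at 6 h. The other 2 had a lower one, CEACAM7 with −0.10 and −0.50 and CEACAM8 with 0.16 and −0.17. The 4 laminin beta chain genes all had higher values at 6 h, with LAMB1 at 0.62, LAMB2 at 0.25, LAMB3 at 0.68 and LAMB4 at 0.45.

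The direction of the deposited ratio was addressed by a prediction written before the data were examined. ROCK inhibition is known to lower targets of SRF with MRTF and of YAP with TAZ, so if the ratio is treated over control, both lists were predicted below the 2.5th percentile on both arrays, and beyond the upper bound of random lists if it is the reverse. The percentiles ranged from 3.77 to 31.8, so neither bound was met and the test does not settle the direction. The hypothesis that negative values may mean lower in treated cells therefore stays open. Of 19 SRF and MRTF targets, 13 were negative at 3 h and 14 at 6 h, and of 17 YAP and TAZ targets 12 and 9 were negative, with TAGLN and AMOTL2 among the negative genes and CCN1 and CCN2 among the positive.

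Housekeeping genes had medians of −0.11 at 3 h and −0.05 at 6 h over 9 genes, with RPLP0 at −1.09 and −1.10.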
